A study of Mus musculus with 12 samples.

How the data were processed

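RNA was measured in the annulus fibrosus (AF) and nucleus pulposus (NP) of lumbar discs, L1 to S1, from 12-month-old C57BL/6 mice. Per the labels, 3 samples came from each of 4 groups: AF and NP of wild-type (WT) mice and of mice with 1 functional copy of Nfat5, the gene of TonEBP (TonEBP +/-). Each sample held the pooled tissue of a single animal, per the labels' protocols. RNA was isolated with RNeasy Mini columns, labelled with the WT Plus kit and hybridized to Clariom S Mouse arrays, per the labels' protocols. The submitters' processing notes name Affymetrix Expression Console and RMA without versions or settings. The deposited values are log2 signals, 1 per probe set and array, made by the authors with RMA. RMA corrects background, equalizes the distribution of signals across the arrays normalized together, and summarizes probes. The notes do not say which arrays were normalized together. AF and NP arrays differed in their medians (7.43 to 7.64 and 6.82 to 6.87 log2), and AF arrays also in their interquartile ranges (2.36 to 3.11, against 3.61 to 3.8 in NP), so changes between the tissues are given relative to the median change.

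Of 28846 probe sets, 22206 transcript clusters were tested. The other 6640 are controls and were left out, among them 23 background and 6546 normalization control probe sets. A gene symbol was found for 19572 clusters, covering 19505 genes, and 2634 clusters have no name here. Names came from the array's gene table and from the RefSeq gene table of GRCm38.p6, used only for names and for the order of neighbouring genes. A cluster was taken as clearly above background on an array where it exceeded the 95th percentile of that array's background probe sets, 7.11 to 7.98 log2, as 41% to 47.1% of clusters did. The background probe sets ran from 2.95 to 8.7 with the GC content of their probes, which is not known here for the clusters, so this level is strict. Where a group had 0 of 3 arrays above it, a change is given against the mean background level of that group (at least, at or below, no less than), and none is given where both groups were so. This reading was chosen after seeing the data. No pair of arrays was a duplicate: the smallest SD of the difference between 2 arrays was 0.414 log2.

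The tests were run in R 4.3.3 with limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. A linear model with a mean for each of the 4 groups was fitted to all 12 arrays, leaving 8 residual degrees of freedom. The spread was moderated by eBayes without an intensity trend (7.93 prior degrees of freedom). Each comparison was adjusted by Benjamini and Hochberg over the 22206 clusters, and a cluster was called at an adjusted p under 0.05. The comparisons were TonEBP +/- against WT in AF, in NP and averaged over both, the interaction of genotype with tissue, and NP against AF in each genotype. The labels give no batch, sex or animal number and do not tie AF and NP samples to the same mouse, so no covariate or block was used. Comparisons, their tests, gene lists and the rule for naming genes were fixed before the data were examined, except for the departures and later additions named below and the tests of technical sources said to be chosen later.

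There were 25 gene lists to test. Those of disc and matrix held osmoprotective genes, NP and notochord markers, AF and tendon markers, cartilage matrix and chondrocyte genes, hypertrophic chondrocyte and mineralisation genes, glycosaminoglycan synthesis enzymes, fibrous matrix and crosslinking genes, and matrix proteases and inhibitors. Those of responses held proinflammatory cytokines and mediators, and actin cytoskeleton, hypoxia response, endoplasmic reticulum stress, interferon response, immediate early and cell cycle genes. Those of other cell types held markers of macrophages, neutrophils and myeloid precursors, erythroid cells, B and plasma cells, T and NK cells, skeletal muscle, endothelium, adipocytes, osteoclasts, and Schwann cells and neurons. A list of sex-linked genes served as a check. Of 420 listed members, 36 had no cluster, and no gene stands in more than 1 list. Where a gene had several clusters (55 genes), the one with the highest mean was used. Each list was set against all other genes with limma's camera at its preset correlation of 0.01, adjusted over the 25 lists. Camera with a correlation estimated from the data, and fry, which tests a list on its own without comparing it with other genes, were run beside it. Counts of members that passed are given over all clusters and, where so stated, adjusted over the list alone. A list's mean change carries the standard error over arrays.

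Genes were named by a rule. Nfat5 is named in every comparison, then the 8 largest rises and 8 largest falls among called clusters with 1 symbol whose groups did not overlap. Where fewer passed, places were filled by the smallest unadjusted p among genes with at least a 1.5-fold change and no overlap, which are said not to pass. For the interaction and the averaged effect, 5 and 5 were named without the overlap condition (for the averaged effect this departs from the rule as fixed, which gave 8 and 8). From a list, up to 4 members with the smallest p may be named. Predicted genes, RIKEN clones, microRNAs, small nucleolar RNAs and olfactory and vomeronasal receptors were left out.

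The fit was tested on simulated data, 10 sets per tissue with the moderated within-group spread of each cluster and 200 changed clusters each among the 22206. Clusters were drawn independently and with equal spread on all arrays of a tissue. Real clusters correlate and AF arrays differ in spread, so the shares of false calls below are no estimate for the real calls. In AF it recovered 41.5% of 2-fold, 98.8% of 4-fold and 100% of 8-fold changes, with 22.2% of calls false. In NP it recovered 35.3%, 99.5% and 100%, with 3.69% false. The median within-group SD was 0.364 log2 in AF and 0.264 in NP, so a spread shared over the tissues is too small for AF and its adjusted p-values are too small. The alternatives tried were other variance priors, array weights, a filter on the dimmest 30% of clusters, renormalization, covariates for marrow and muscle markers, each comparison's own arrays alone, other thresholds, and leaving out each array in turn. An interquartile range covariate, subtraction of the background median and a restriction to clusters above background were added after seeing the data. The calls were also compared with those from other splits of the same arrays.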

Results

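The data describe 2 compartments of the ageing mouse lumbar disc: the AF, its fibrous outer ring, and the NP, its proteoglycan-rich core. In each tissue, 3 samples of 12-month-old WT mice stand beside 3 of TonEBP +/- mice. TonEBP is the transcription factor through which cells adapt to high osmolarity, and the series asks how its partial loss bears on matrix, cytoskeletal and proinflammatory genes during age-related degeneration. Array medians were 7.43 to 7.64 log2 in AF and 6.82 to 6.87 in NP, and the number of arrays, 3 per group, limits the precision. Tissue held most of the variance (first principal component 83.4%, second 6.33%). Replicates correlated at 0.966 to 0.976 in AF of WT, 0.942 to 0.969 in AF of TonEBP +/-, and 0.985 to 0.988 in NP. AF array 3 of TonEBP +/- stood apart from the other AF arrays, with an interquartile range of 3.11 log2 against 2.36 to 2.66.

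**Figure D1:**
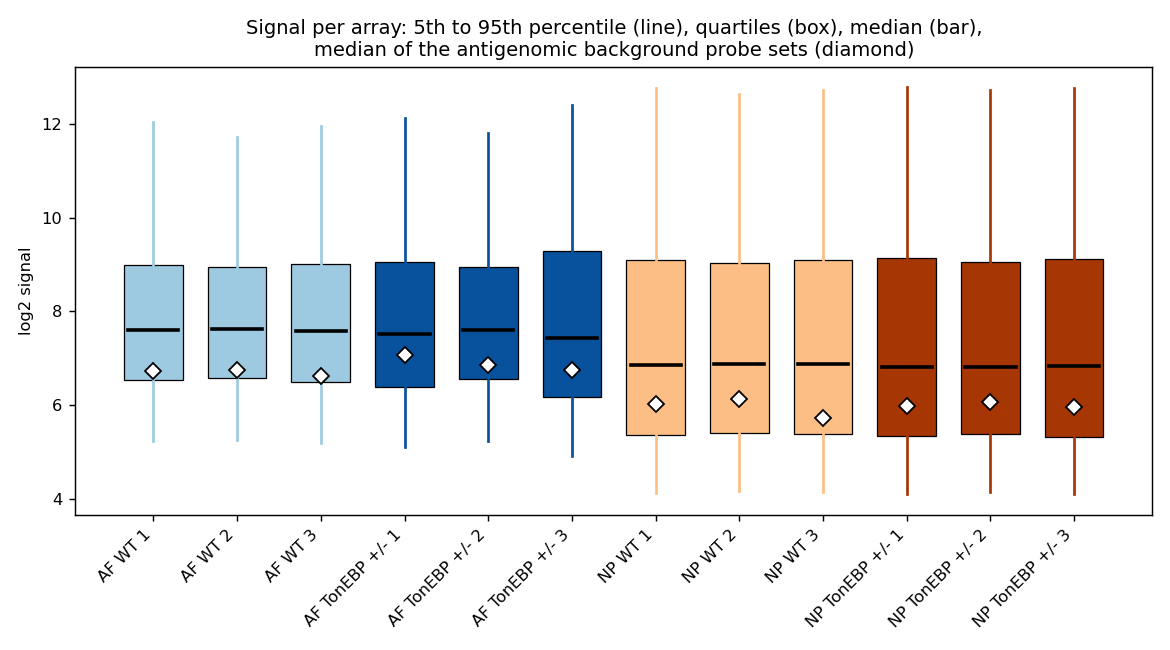
Log2 signal of the tested transcript clusters on each of the 12 arrays (line, 5th to 95th percentile; box, quartiles; bar, median), with the median of the 23 background probe sets as a diamond. NP arrays have lower medians and wider quartiles than AF arrays.

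Nfat5 itself, the gene with 1 copy lost, was measured first. Its log2 signal in AF was 7.70, 8.69 and 9.94 in WT and 8.91, 8.94 and 8.74 in TonEBP +/-. In NP it was 9.12, 8.80 and 8.34 in WT and 9.06, 9.62 and 9.09 in TonEBP +/-. The difference between genotypes was 0.09 log2 in AF (95% CI -0.77 to 0.94, limma adjusted p = 0.923) and 0.50 in NP (95% CI -0.35 to 1.36, adjusted p = 1). Both intervals lie above a 2-fold loss, which would be -1 log2. The AF interval uses the spread shared over the tissues, which is too small for AF. With WT arrays from 7.70 to 9.94 there, a 2-fold loss in AF is not excluded. In AF of WT it was clearly above background on 2 of 3 arrays. Whether the probes lie in the deleted part of the gene is not known, so these values may check nothing about the labels.

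In AF of TonEBP +/- mice, the type I collagen genes, 7 of 10 mineralisation genes and 3 of 8 osteoclast markers rose, and 2 of 21 cartilage genes, Acan and Sox9, fell (limma, n = 3 per genotype). As lists, mineralisation and osteoclast genes had adjusted p = 0.276 and cartilage genes adjusted p = 0.534 with an estimated correlation. Col1a1 and Col1a2, the chains of type I collagen, rose 18.1-fold (log2 4.18, SE 0.645) and 13.0-fold (3.70, SE 0.695), and Tnc, the matrix glycoprotein tenascin C, 13.8-fold (3.78, SE 0.530). The osteoclast enzymes Acp5 and Ctsk and the proton pump subunit Atp6v0d2 rose 17.6-, 12.3- and 10.9-fold, the collagenase Mmp13 11.5-fold, and the chemokine Cxcl12 8.38-fold. The largest falls were in the secreted serine protease Htra1 (6.51-fold; log2 -2.70, SE 0.245), the protease inhibitor Serpina1e (5.28-fold), the NP keratin Krt19 (4.57-fold), the mitochondrial protein gene Ndufa4l2 (4.32-fold) and the collagen-binding proteoglycan Fmod (4.31-fold). Inmt, a methyltransferase, Aspn, a small leucine-rich proteoglycan, and Cdon, a Hedgehog co-receptor, fell 4.24-, 4.16- and 4.11-fold. For each of these genes all 3 TonEBP +/- arrays lay beyond all 3 WT arrays, as the naming rule required. Their limma adjusted p ran from 0.000162 (Htra1) to 0.0476 (Krt19). Krt19 and Aspn were clearly above background on 1 of 3 AF arrays of TonEBP +/- mice, and Ctsk and Atp6v0d2 on 2 of 3 of WT mice, so their folds and order are not exact.

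In all, 1347 of 22206 clusters were called in AF, 612 higher and 735 lower (45.4% higher), and 1094 of them changed at least 2-fold. Of the 1347, 114 were clearly above background on no AF array. With array medians subtracted there were 1276, 713 higher and 563 lower (55.9% higher), so which direction prevails depends on the scaling. At an unadjusted p under 0.05 there were 5158, where chance gives 1110. The spread shared over the tissues is too small for AF, which makes these adjusted p-values too small. On simulated data 22.2% of calls were false, but without correlated clusters or arrays of unequal spread, so the false share of the real calls is not known. The count fell to 81 without AF array 3 of TonEBP +/- and to 267 without array 1, rose to 4029 without array 2, and was 463, 193 and 576 without AF WT arrays 1, 2 and 3. It was 3 from the AF arrays alone, 15 with marrow and muscle marker covariates and 38 with the interquartile range as a covariate. Of the 51 genes named as passing in AF, 13 kept an adjusted p under 0.05 in every omission of 1 array: Acan, Atp6v0d2, Cdon, Col1a1, Cxcl12, Fmod, Fn1, Htra1, Ibsp, Mmp13, Ndufa4l2, Serpina1e and Tnc. These omissions still use the spread shared over the tissues. Of the 13, only Acan, Htra1 and Ibsp also kept their call in all 11 other settings, the AF arrays alone among them. The others kept it in 8 to 10 of 11.

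Among the lists, hypertrophic chondrocyte and mineralisation genes stood out in AF, with 7 of 10 measured members higher (8 adjusted over the list alone) and a mean change of 1.58 log2 (SE 0.467, camera adjusted p = 2.44e-07). Besides Mmp13, they included the bone sialoprotein Ibsp (log2 3.00, SE 0.325), osteocalcin Bglap (2.5) and the endopeptidase Phex (1.57). Osteoclast markers rose by a mean of 1.6 (SE 0.540; 3 of 8 members, adjusted p = 0.000437) but a median of 0.57: Acp5, Ctsk and Atp6v0d2 carry the mean, and 4 of the 8 were clearly above background on no AF array. For both lists adjusted p = 0.276 with an estimated correlation, and both passed fry (adjusted p = 0.024). Cartilage matrix and chondrocyte genes fell as a list (mean -0.57, SE 0.535; 2 of 21 lower, 3 over the list alone, adjusted p = 0.00217), with adjusted p = 0.534 with an estimated correlation. AF WT array 1 was as low for this list (10.5) as the lowest TonEBP +/- array (10.5), beside 11.8 and 12.1 on WT arrays 2 and 3: the mean was -1.05 without array 1 and -0.28 without array 3, where the list did not pass (adjusted p = 0.117). Their called members were Acan, the core protein of aggrecan (log2 -2.03, SE 0.204), and its regulator Sox9 (-1.55), while Cytl1, a cytokine-like chondrocyte gene, was at -1.06 (adjusted p = 0.0726) and at the array maximum on 2 AF arrays. NP and notochord markers were lower (mean -0.47; 1 of 17, adjusted p = 0.0465), through Krt19, with the keratin Krt8 at -1.26 (adjusted p = 0.101); for the list adjusted p = 0.395 with an estimated correlation. Its mean was -0.23 without AF WT array 1 (adjusted p = 0.162), and the list did not pass without WT array 3 or TonEBP +/- array 2 either (0.0566 and 0.318).

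Some lists of cells found in marrow rose in AF and others did not pass (erythroid markers, mean -0.17, and B and plasma cell markers, 0.14). Those that rose were neutrophil and myeloid precursor markers by 1.00 (SE 0.244; 4 of 14, 6 over the list alone, adjusted p = 9.19e-05) and macrophage markers by 0.74 (2 of 14, 5 over the list alone; 0.00186). Cell cycle genes, which mark no cell type, rose by 0.81 (2 of 15, 3 over the list alone; 9.58e-06). With an estimated correlation adjusted p = 0.495, 0.383 and 0.495 for these 3 lists. The members called were Camp, an antimicrobial peptide (log2 2.11), Cebpe, a granulocyte transcription factor (at least 1.19), the granule proteases Prtn3 (1.47) and Ctsg (1.38), the ribonucleotide reductase subunit Rrm2 (1.21), the mitotic kinase Bub1 (1.14), the receptor Csf1r (1.98) and Aif1 (at least 0.533), where at least means against the background level. The macrophage list did not pass among clusters above background alone (adjusted p = 0.255). As a measured fact, neutrophil markers were at a mean of 15.7 to 16.2 on AF WT arrays and 16.7 to 17.4 on AF TonEBP +/- arrays. AF array 3 of TonEBP +/-, the array that stood apart, was the highest AF array for the neutrophil (17.4), cell cycle (12.1), macrophage (10.3), osteoclast (10.2), actin (12.2), endoplasmic reticulum stress (11.9) and endothelial (8.49) lists and among the lowest for the cartilage list. Without it the cell cycle mean was 0.47 (adjusted p = 0.00153).

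Actin cytoskeleton genes rose in AF (mean 0.56, SE 0.278; 8 of 31 higher, 16 over the list alone and 1 lower, adjusted p = 4.13e-05), among them transgelin 2 Tagln2 (1.43), moesin Msn (1.34), tropomyosin Tpm1 (1.27) and vinculin Vcl (1.10). Endoplasmic reticulum stress genes (0.48; 1 of 13, the transcription factor Xbp1 at 1.38, adjusted p = 0.0183) and endothelial markers (0.49; 1 of 11, the VEGF receptor Kdr at no less than 1.44 against the background level, adjusted p = 0.0328) rose as well. With an estimated correlation adjusted p = 0.495 for actin and 0.534 for the other lists. Without AF TonEBP +/- array 3 the means were 0.34 for actin (adjusted p = 0.000992), 0.19 for endoplasmic reticulum stress (0.265) and 0.28 for endothelial markers (0.258). Without AF WT array 1 neither of the latter lists passed (0.059 and 0.111), and endothelial markers did not pass without WT array 3 (0.123) or TonEBP +/- array 2 (0.0888). Neither passed among clusters above background alone (0.255 and 0.726).

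Other lists did not pass in AF, although single members did. Fibrous matrix and crosslinking genes had a mean of 0.24 (5 of 22 higher, 3 lower, adjusted p = 0.511): besides Tnc, the collagen chaperone Serpinh1 (1.56) and the collagen chain Col5a2 (1.30) rose and fibronectin Fn1 fell (-1.57). Matrix proteases and inhibitors had 0.38 (5 of 21 higher, 1 lower; 0.0992), with the membrane collagenase Mmp14 (at least 1.6) and cathepsin B, Ctsb (1.24), higher. The inhibitor Timp1 was called but clearly above background on 1 of 6 AF arrays, so no change is given. Proinflammatory cytokines and mediators had 0.16 (2 of 28 higher, 1 lower; 0.608): Cxcl12 and the interleukin 1 receptor antagonist Il1rn (1.48) rose and the syndecan Sdc4 fell (-1.67). Osmoprotective genes had 0 of 10 called (limma, mean -0.05, median 0.25, adjusted p = 0.777). Of the direct targets of TonEBP in this list, Akr1b3 and Slc5a3 were not analysed here. The betaine transporter Slc6a12 (adjusted p = 0.101) was clearly above background on 2 of 3 AF arrays of WT and 0 of 3 of TonEBP +/-, and the heat shock gene Hspa4l (0.0888) on 0 and 2. AF and tendon markers had 3 of 15 higher and 1 lower (0.76): Lum, a collagen-binding proteoglycan, rose by 1.62 beside the type I collagen genes while Fmod fell, and the mean (0.14) and median (-0.26) differ in sign. Glycosaminoglycan synthesis enzymes had -0.12 (0.511), with the xylosyltransferase Xylt1 lower (-1.0) and the chondroitin synthase Chsy1 higher (0.85).

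The remaining AF lists, with mean and adjusted p, were hypoxia response genes (-0.09, 0.608; Ankrd37 lower by at least 0.455), interferon response genes (0.07, 0.76; the antiviral tetherin Bst2 higher at 1.33), immediate early genes (-0.23, 0.511), erythroid markers (-0.17, 0.608) and B and plasma cell markers (0.14, median -0.06, 0.76; the antibody joining chain Jchain higher at 1.68). T and NK cell markers (-0.02, 0.752; the granule gene Nkg7 higher at 1.28), skeletal muscle markers (-0.22, 0.0992), adipocyte markers (0.30, median -0.06, 0.608; the fatty acid binding protein Fabp4 higher at 1.88) and Schwann cell and neuron markers (-0.29, 0.15) did not pass.

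**Figure D2:**
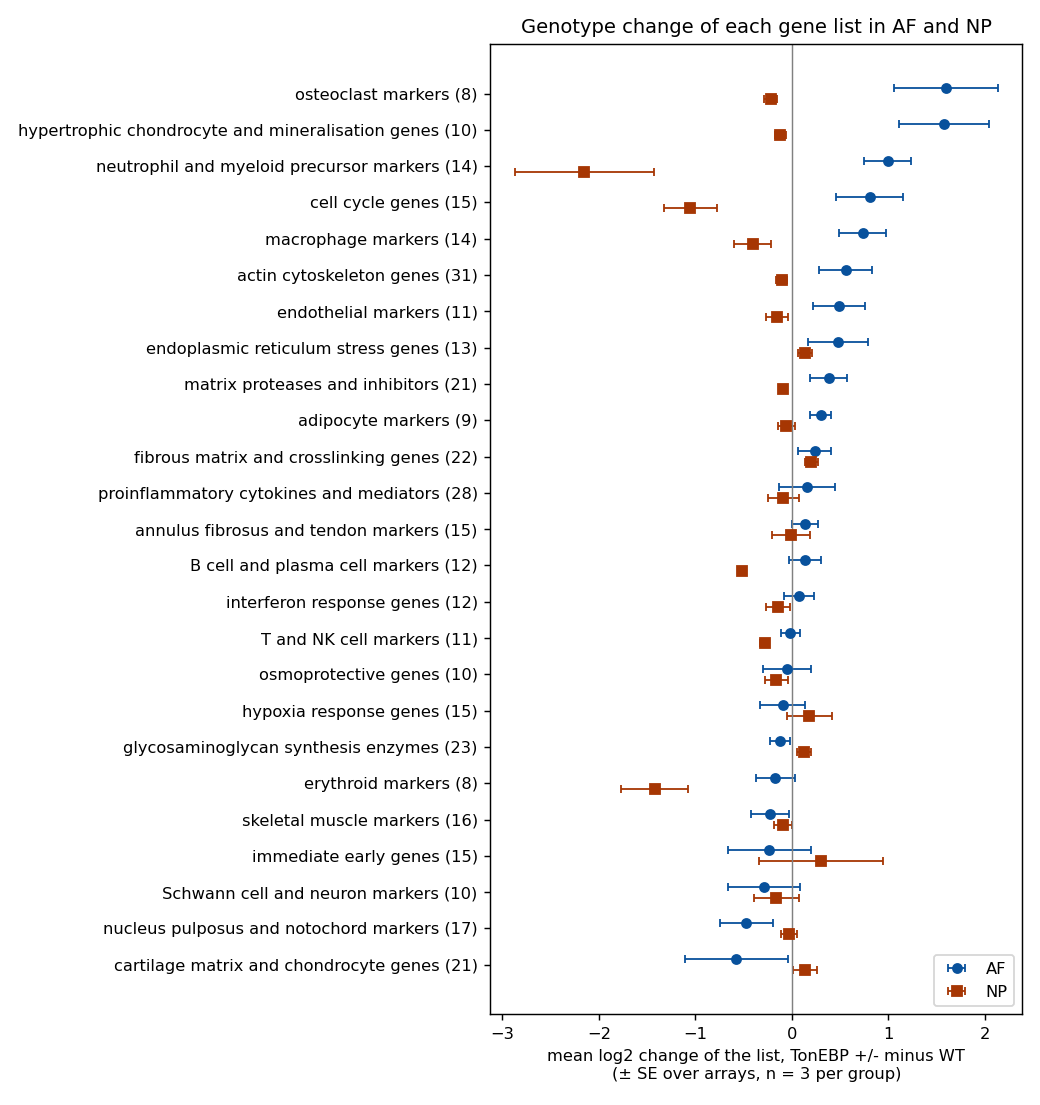
Mean log2 change of each gene list between TonEBP +/- and WT in AF (circles) and NP (squares), with the standard error over arrays (n = 3 per group); measured members in brackets. Mineralisation and osteoclast lists have the largest positive means in AF, and the neutrophil and erythroid lists the largest negative means in NP.

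In NP of TonEBP +/- mice, genes of blood-forming and immune cells fell, and no gene rose (n = 3 per genotype). The largest falls were in Ctse, an aspartic protease of blood and immune cells (12.6-fold; log2 -3.66, SE 0.417), the neutrophil granule enzymes Mpo (10.1-fold; -3.33, SE 0.432) and Elane (9.25-fold; -3.21), the ubiquitin conjugating enzyme Ube2l6 (at least 4.04-fold against the background level) and the red cell anion exchanger Slc4a1 (8.16-fold; -3.03, SE 0.420). Ly6e, a surface antigen, the proliferation marker Mki67 and Nxpe2 fell 7.77-, 7.44- and 6.54-fold, the lysozyme Lyz2 5.82-fold and the granule protease Ctsg at least 1.97-fold. Limma adjusted p ran from 0.00383 (Ctse) to 0.0401 (Ube2l6). No gene passed upwards: the smallest p belonged to the synapsin Syn3 (adjusted p = 0.127), the kallikrein Klk10 (log2 0.97), the secreted Ly6 protein Slurp1 (1.45), Txndc11, the phosphodiesterase Pde1b (1.03), the basement membrane collagen Col18a1 (1.02), Cmtm5 (1.13) and Lrrc72, with adjusted p of 0.143 to 0.485 beyond Syn3. Syn3, Txndc11 and Lrrc72 were clearly above background on no NP array, so no change is given for them.

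In all, 25 clusters were called in NP, 0 higher and 25 lower by limma, and 827 had an unadjusted p under 0.05, where chance gives 1110. The count was 2 and 16 without NP TonEBP +/- arrays 2 and 1, 7, 6 and 79 without NP WT arrays 1, 2 and 3, 12 and 41 without AF TonEBP +/- arrays 1 and 2, and 14, 13 and 12 without AF WT arrays 1, 2 and 3. It was 0 from the NP arrays alone and 0 with marrow and muscle marker covariates, and 13 with array medians subtracted. Of 10 genes named as passing, Ctse and Mpo passed in every omission of 1 array. Of the 25 clusters, 22 (88%) were higher in AF than in NP of WT mice, as were 31.3% of all clusters with array medians subtracted and 56.1% as deposited (88% of the 25 under both).

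Neutrophil and myeloid precursor markers fell by a mean of 2.15 log2 in NP (SE 0.722; 3 of 14 called, 13 over the list alone, adjusted p = 1.43e-36), with the chitinase-like Chil3 at -2.67 (adjusted p = 0.0656). Erythroid markers fell by 1.42 (SE 0.351; 1 of 8, 8 over the list alone, adjusted p = 3.83e-22), with the red cell membrane gene Rhag at or below -1.17 (0.0781). Cell cycle genes fell by 1.05 (SE 0.273; 1 of 15, 8 over the list alone, adjusted p = 3.64e-22), with Ube2c at or below -0.872 (0.0656) and Rrm2 at -1.33 (0.127). These 3 lists passed with an estimated correlation as well (adjusted p = 0.014 for the neutrophil and erythroid lists, 0.0431 for the cell cycle). They did so too among clusters above background alone, with 13, 4 and 5 members (adjusted p = 0.0145, 0.0145 and 0.018). Of these members, 13, 4 and 5 were above background on all 3 WT arrays but 10, 3 and 1 on all 3 TonEBP +/- arrays. The filter thus partly follows the fall itself and adds little support. The B and plasma cell list was also called (mean -0.51, SE 0.0214; 0 of 12 by limma, adjusted p = 2.01e-07, and 0.014 with an estimated correlation), but 11 of its 12 members, Cd79a among them, were clearly above background on no NP array, so this is not read as a fall. No list of another comparison passed with an estimated correlation. Macrophage markers (mean -0.41; 1 of 14, with Mpeg1 at or below -0.771, adjusted p = 0.257), T and NK cell markers (-0.28; 9 of 11 above background on no NP array) and fibrous matrix genes (0.20, with the crosslinking enzyme Loxl3 at 0.93 and Col6a2 at 0.52, neither passing) each had adjusted p = 0.0057. With an estimated correlation their adjusted p = 0.273, 0.0534 and 0.318. Macrophage markers were at -0.26 without NP WT array 1 (adjusted p = 0.116) and fibrous matrix genes at 0.14 without NP TonEBP +/- array 2 (0.0889). The T and NK cell list did not pass among clusters above background alone (0.832). There the macrophage list passed on 3 members with an estimated correlation too (0.0425), 3 of them above background on all 3 WT arrays and 2 on all 3 TonEBP +/- arrays.

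Cartilage, mineralisation, notochord, hypoxia, actin and cytokine lists did not pass in NP: the other 18 lists had adjusted p of 0.116 to 0.871. NP and notochord markers had a mean of -0.03 (SE 0.085) and cartilage genes 0.14 (SE 0.127). The cartilage list passed among clusters above background alone (0.30, adjusted p = 0.0337, and adjusted p = 0.775 with an estimated correlation). Osmoprotective genes had -0.16 (adjusted p = 0.149), with the water channel Aqp1 at or below -0.6 (adjusted p = 0.0656). For Schwann cell and neuron markers the mean (-0.16) and median (0.01) differ in sign.

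The interaction asks whether the genotype change differs between the tissues, as the change in NP minus that in AF. Neutrophil genes, whose mean was higher in AF and lower in NP, made up 3 of the 5 most negative values of named genes that passed: Elane (log2 -4.91, SE 0.746), Camp (at or below -3.98) and Mpo (-4.32), with Ncf1, a subunit of the phagocyte oxidase (-4.39), and the histone gene H2ac15 (-4.71). Htra1 (2.85, SE 0.347), Slurp1 (2.83), Serpina1e (2.66), Sbsn (at least 1.92) and the annexin Anxa8 (2.31) gave the largest positive values as measured. Acan (2.13) and Fn1 (1.89) were positive, and Mki67 (-3.47), Rrm2 (-2.55), Lyz2 (-3.49), Ctsg (at or below -2.36), Jchain (at or below -1.81), Slc4a1 (-2.88) and Aqp1 (at or below -0.982) negative. Ibsp, Mmp13, Tnc, Atp6v0d2 and the erythroid gene Hemgn passed and Acp5 did not (adjusted p = 0.0537), but all 6 were clearly above background on no NP array. A change in NP cannot be read for them, so their negative values say no more than the change in AF. Limma adjusted p ran from 0.00687 to 0.0421 for the genes that passed. Nfat5 was at 0.42 (adjusted p = 0.807).

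In all, 197 clusters passed the interaction, 27 positive and 170 negative (48 and 147 with quantile normalization across all arrays), of which 38 were clearly above background on no NP array, and 3119 had an unadjusted p under 0.05, where chance gives 1110. The count was 81, 1319 and 85 without AF TonEBP +/- arrays 1, 2 and 3, 24 and 74 without AF WT arrays 2 and 3, 79, 29 and 114 without NP TonEBP +/- arrays 1, 2 and 3, 48 and 22 without NP WT arrays 1 and 2, and 0 with marrow and muscle marker covariates. Of 24 genes named as passing, Acan, Camp, Ctsg, Elane, Htra1, Ibsp, Mki67 and Mpo passed in every omission of 1 array. Of the lists, neutrophil (mean -3.15, SE 0.762), cell cycle (-1.86), osteoclast (-1.82), mineralisation (-1.70), erythroid (-1.25), macrophage (-1.14), actin (-0.66), B cell (-0.65) and endothelial (-0.64) lists were negative and the cartilage list positive (0.71), with adjusted p of 2.77e-20 (neutrophil) to 0.00882 (endothelial). With an estimated correlation adjusted p = 0.105 to 0.351. The cartilage mean was 1.19 without AF WT array 1 and 0.42 without AF WT array 3, and without AF TonEBP +/- array 3 the actin mean was -0.44 and the endothelial list did not pass (-0.43, adjusted p = 0.0521). Of the mineralisation, osteoclast, B cell and endothelial lists, 9 of 10, 7 of 8, 11 of 12 and 10 of 11 members were clearly above background on no NP array, so these values say little about NP. Among clusters above background in both tissues, neutrophil, cell cycle, macrophage, erythroid and actin lists passed as negative, and cartilage, NP and notochord, glycosaminoglycan, fibrous matrix, hypoxia and immediate early lists as positive. None of these 11 passed there with an estimated correlation (adjusted p = 0.193 to 0.498). The osteoclast list, with 1 member left, did not pass (0.22), and the mineralisation, B cell and endothelial lists had no member left. The other 15 lists had adjusted p of 0.0638 to 0.959.

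**Figure D3:**
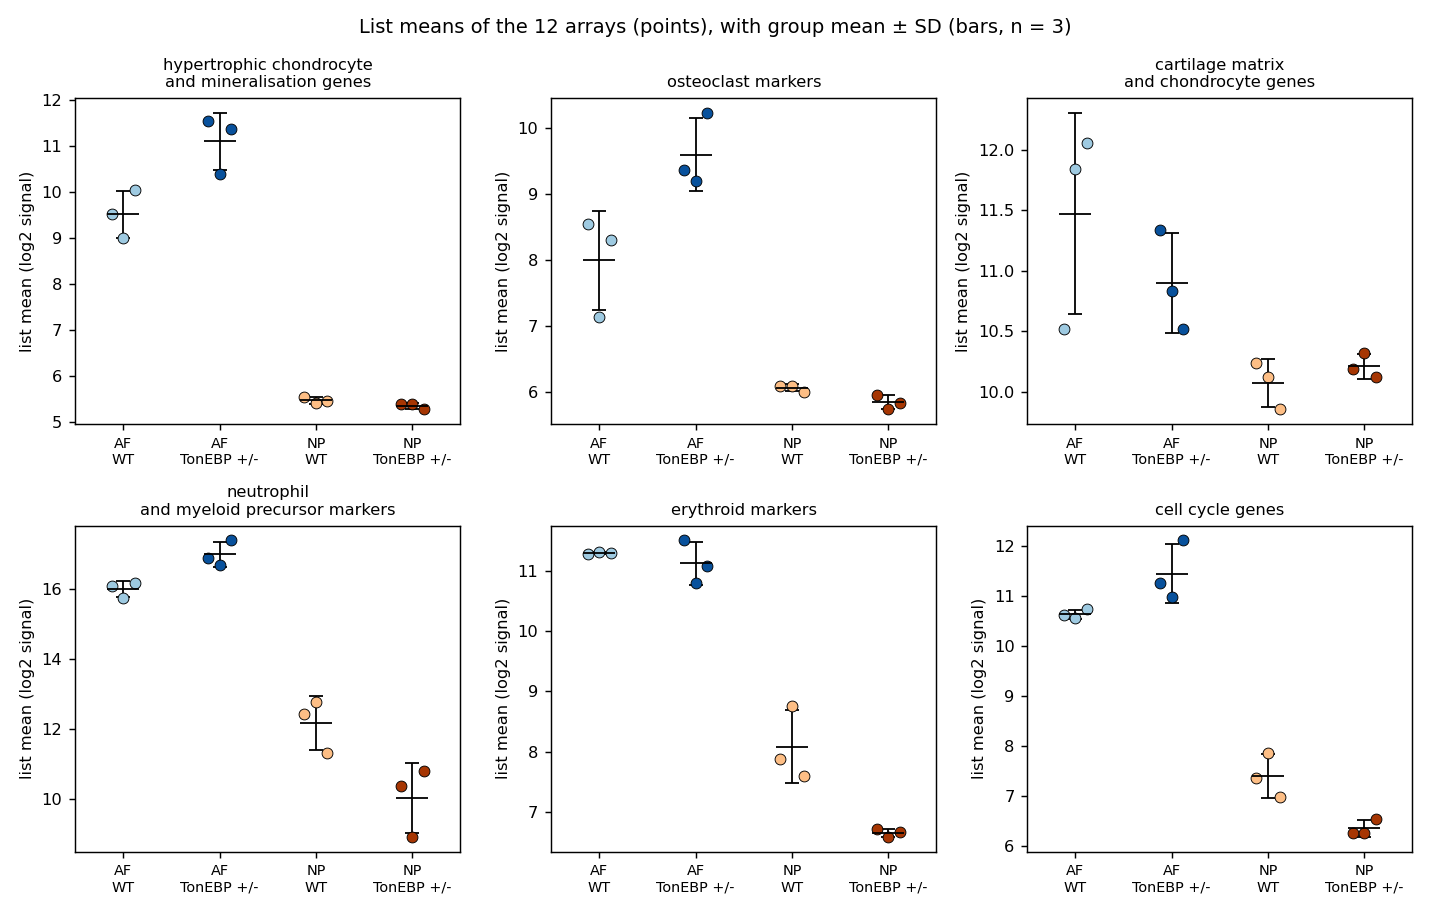
Mean log2 signal of 6 gene lists on each of the 12 arrays (points), with group mean and SD (n = 3 per group). Neutrophil markers are higher in AF and lower in NP of TonEBP +/- mice than of WT mice.

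Averaged over AF and NP, 1 gene was called: Htra1, lower by 1.28 log2 (SE 0.173, limma adjusted p = 0.0358). It combines a fall of 2.70 in AF with a change of 0.15 in NP, so the averaged value describes neither tissue. Those nearest to passing were Acan (-0.97, adjusted p = 0.055), Ibsp (1.31), the coactivator Ncoa6 (0.91), Ctse (-1.68), Ndufa4l2 (-1.02) and Tmcc2 (-1.49), each with 0.119 (for Ibsp, above background on no NP array, the value says no more than AF), the mitotic checkpoint gene Bub3 (0.82, 0.129), and the respiratory chain gene Cox6c (0.81) and the proteasome subunit Psmd6 (0.85), with 0.130. At an unadjusted p under 0.05 there were 3159. The count was 1033 without AF TonEBP +/- array 2, 7 without AF WT array 1, 1 without AF TonEBP +/- array 3 and 0 without any of the other 9 arrays. Nfat5 was at 0.30 (adjusted p = 0.683).

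Erythroid markers were lower on average over the tissues (mean -0.80, SE 0.203; 0 of 8 by limma, 7 over the list alone, adjusted p = 3.22e-08), with Slc4a1 at -1.59 and the heme synthesis enzyme Alas2 at -1.45 (adjusted p = 0.130 and 0.135). Mineralisation (0.73), osteoclast (0.69), endoplasmic reticulum stress (0.31), actin (0.23) and fibrous matrix (0.22) lists were higher and neutrophil (-0.58) and B cell (-0.19) lists lower, with adjusted p of 3.34e-06 to 0.0343. With an estimated correlation adjusted p = 0.296 to 0.6 for these 8 lists. Without AF TonEBP +/- array 3 the endoplasmic reticulum stress list did not pass (0.17, adjusted p = 0.0526) and the actin mean was 0.12. The neutrophil list did not pass without AF TonEBP +/- array 2 (0.0658) and was at -0.30 without NP TonEBP +/- array 2. Fibrous matrix genes did not pass without AF WT array 1 (0.14, adjusted p = 0.346), AF TonEBP +/- array 2 (0.1) or NP TonEBP +/- array 2 (0.0669), nor B cell markers without AF WT arrays 1 or 3 or AF TonEBP +/- arrays 1 or 2 (0.0518 to 0.1). Endoplasmic reticulum stress (adjusted p = 0.107), osteoclast (0.19) and fibrous matrix lists (mean 0.07, 0.533) did not pass among clusters above background in both tissues, where the mineralisation and B cell lists had no member left. Of these, 9 of 10 and 11 of 12 members were clearly above background on no NP array, so their averages say no more than AF. The erythroid, neutrophil and actin lists passed there, as did NP and notochord, cartilage and cell cycle lists, all lower, but none with an estimated correlation (adjusted p = 0.269 to 0.642). The other 17 lists had adjusted p of 0.0555 to 0.974.

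The genotype changes of AF and NP shared 5 called clusters, where 1.52 are expected if clusters and the tests in AF and NP are independent (Fisher's exact p = 0.0157). Both tests of a cluster use the same estimate of its spread, so they are not independent and this p may be too small. All 5 were higher in AF and lower in NP: Ctsg, Ly6c2, a monocyte surface antigen, Clec12a, a myeloid receptor, Fermt3, an integrin adaptor of blood cells, and Atp8b4. Apart from Ctsg these were named after their values were seen. Across all clusters the changes in AF and NP correlated at -0.0976 (Spearman 0.0181). At an unadjusted p under 0.05 in each tissue, 320 were shared, 54 in the same and 266 in opposite directions, where 192 are expected under the same assumption.

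NP and AF of WT mice differed in most genes. Relative to the median change, the smooth muscle actin Acta2 (log2 9.68, SE 0.352), the galectin Lgals3 (9.11), Krt19 (9.03), the glypican Gpc3 (9.02), the phosphodiesterase Pde1a (9.02), Krt8 (8.98), the imprinted gene Zim1 (8.98) and Tmem255a (8.98) were highest in NP. Higher in AF were the collagen-binding proteoglycans Dcn (-9.09, SE 0.909) and Chad (-7.98), the lubricin gene Prg4 (-7.90), Clec3a (-7.90), the cartilage oligomeric protein Comp (-7.54), the thrombospondin Thbs1 (-7.03), chondromodulin Cnmd (-7.00) and Col1a2 (-6.30). Dcn was at the array maximum on 2 AF arrays and Prg4 on 1, counted over both genotypes, so their differences in WT may be larger than measured. Acta2 and Gpc3 were clearly above background on 1 of 3 AF arrays and Tmem255a on 2, and in NP Clec3a, Cnmd and Col1a2 on 1 and Dcn, Comp and Thbs1 on 2, so the order of these genes is not exact. Limma adjusted p was at most 1.80e-06 for all of these genes, and no AF array overlapped an NP array, as the naming rule required.

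In WT, 17387 of 22206 clusters were called, 4921 higher in NP and 12466 higher in AF. The median cluster was 0.84 log2 lower in NP, and the background probe sets, which match no gene, 0.64 lower. With array medians subtracted 14423 were called, 7473 higher in NP and 6950 higher in AF, with background medians subtracted 13733 (7212 and 6521) and with quantile normalization across all arrays 12093 (6020 and 6073), so the split depends on the scaling. Of the 17387, 7397 were clearly above background on none of these arrays, and of 10993 clusters above background 8237 were called, 4522 higher in NP and 3715 higher in AF. All 47 genes named as passing did so in every omission of 1 array.

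By group, and relative to the median change, hypoxia response genes were higher in NP of WT (mean 3.82, SE 0.195; 12 of 15, adjusted p = 2.09e-07), with the mitophagy gene Bnip3 (6.07), the oxygen sensors Egln3 (7.07) and Egln1 (5.23) and Ndrg1 (6.36). NP and notochord markers (3.35; 10 of 17 higher, 5 lower; 0.000826; Krt18 at 7.91 and the adhesion molecule Ncam1 at 6.28), actin genes (2.06; 15 of 31 higher, 11 lower; 0.000826; Tagln at 6.74 or more and Cnn3 at 5.17) and glycosaminoglycan enzymes (1.5; 12 of 23 higher, 6 lower; 0.00663) were higher too. Of the last, the sulfate donor synthase Papss1 (5.05), Ugdh (4.97) and Xylt1 (3.87) were higher and the sulfotransferase Chst15, above background on 1 of 3 NP arrays, lower (-2.37). With an estimated correlation adjusted p = 0.118, 0.0847, 0.317 and 0.0847 for these 4 lists. Krt18 was clearly above background on 1 of 3 AF arrays. The actin (0.172) and glycosaminoglycan (0.066) lists did not pass among clusters above background alone.

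Lists higher in AF of WT were mineralisation (-3.21; Ibsp at or below -5.01, Mmp13 at or below -3), neutrophil (-2.99; Camp at -4.13, Mpo at -3.51), cell cycle (-2.41; Mki67 at -3.79), erythroid (-2.37; Hemgn at or below -1.41, Epb42 at -2.42), B cell (-1.62; Cd79a at or below -1.22), macrophage (-1.34; Lyz2 at -4.02), T and NK cell (-1.04), endothelial (-0.91; Pecam1 at or below -0.5, but the VEGF receptor Flt1 at 4.36 or more) and skeletal muscle (-0.56). The muscle actin gene Acta1 passed but was clearly above background on 1 of 3 AF and 0 of 3 NP arrays, so no change is given. The 9 lists had adjusted p of 0.000151 to 0.0313, and with an estimated correlation adjusted p = 0.0847 to 0.322. The list means include members not above background in NP: 10 of 10 for mineralisation, 11 of 12 for B cell, 9 of 11 for T and NK cell, 10 of 11 for endothelial, 14 of 16 for muscle, 8 of 14 for macrophage, 5 of 15 for cell cycle, 3 of 8 for erythroid and 1 of 14 for neutrophil genes. Muscle markers did not pass among clusters above background alone (0.173, 1 member) and AF and tendon markers did, higher in AF (0.00284, and adjusted p = 0.133 with an estimated correlation). The other 12 lists had adjusted p of 0.0564 to 0.885. Among them, osmoprotective genes held the betaine transporter Slc6a12 (6.11) and the cotransporter Slc12a2 (7.91), higher in NP, and Aqp1 (-3.30), higher in AF. AF and tendon markers held Lum (at or below -3.09), higher in AF, but Fmod (4.35), higher in NP, and the cartilage list Acan (3.60) and Sox6 (3.76), higher in NP, beside Comp. Deposited and relative means differ in sign for fibrous matrix (-0.77 and 0.07), matrix protease (-0.59 and 0.24), interferon (-0.52 and 0.32) and endoplasmic reticulum stress genes (-0.05 and 0.79).

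In TonEBP +/- mice the same comparison gave 16510 clusters, 4437 higher in NP and 12073 higher in AF, with a median of -0.75 log2. With array medians subtracted there were 12478, 6854 higher in NP and 5624 higher in AF, with background medians subtracted 11086 (7510 and 3576) and with quantile normalization across all arrays 10866 (5490 and 5376). Of 15106 clusters called in both genotypes, 15100 changed in the same direction, and the changes correlated at 0.922. Of the 16510, 7108 were clearly above background on none of these arrays, and of 10642 clusters above background 7435 were called, 4052 higher in NP and 3383 higher in AF. Relative to the median, Krt19 (11.10, SE 0.618), Zim1 (at least 9.82), Krt8 (10.25), Pde1a (10.16), Tmem255a (9.87), Acta2 (9.64), the imprinted Peg3 (9.58) and Gpc3 (9.52) were higher in NP. Krt19, Krt8, Acta2 and Gpc3 were clearly above background on 1 of 3 AF arrays and Pde1a, Tmem255a and Peg3 on 2, so these differences are not exact and have no order. Higher in AF were Col1a1 (-8.21), the phagocyte oxidase subunit Cybb (-8.10) and Col1a2 (-10.34, SE 0.695; above background on 1 of 3 NP arrays). Camp (at or below -8.2), Ibsp (-8.14), Acp5 (-7.56), Tnc (-7.1) and Mmp13 (-6.66) were clearly above background on no NP array of TonEBP +/- mice, so these 5 values are bounds against the background level. Limma adjusted p was at most 2.47e-08, and all 27 genes named as passing did so in every omission of 1 array.

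Lists higher in NP of TonEBP +/- were hypoxia (4.00; Bnip3 at 6.86, Egln3 at 7.05), NP and notochord (3.70; Krt18 at 8.54) and glycosaminoglycan (1.65; Papss1 at 4.85, Ugdh at 5.14). Lists higher in AF were neutrophil (-6.23; Mpo at -7.92), mineralisation (-5.00), cell cycle (-4.36; Mki67 at -7.34), erythroid (-3.72; Slc4a1 at -6.04), osteoclast (-3.01; Atp6v0d2 at or below -4.33), macrophage (-2.57), B cell (-2.36), endothelial (-1.64), T and NK cell (-1.40), cytokine (-0.92) and skeletal muscle (-0.51). Adjusted p ran from 5.47e-08 to 0.049, and with an estimated correlation adjusted p = 0.0595 to 0.370. The cytokine list did not pass without AF TonEBP +/- arrays 1 or 3, AF WT array 3 or NP WT array 3 (0.0526 to 0.0895), nor the muscle list without AF TonEBP +/- array 1 (0.0531). Members above background on no NP array of TonEBP +/- were 16 of 16 for muscle, 12 of 12 for B cell, 9 of 10 for mineralisation, 10 of 11 for T and NK cell, 10 of 11 for endothelial, 7 of 8 for osteoclast, 11 of 15 for cell cycle, 10 of 14 for macrophage, 5 of 8 for erythroid, 15 of 28 for cytokine and 4 of 14 for neutrophil genes, so these means are not exact. With clusters above background alone the cytokine list did not pass (0.149), AF and tendon markers did, higher in AF (0.00453, and adjusted p = 0.117 with an estimated correlation), and the muscle list had no member. The other 11 lists had adjusted p of 0.0578 to 0.647. Osmoprotective genes were among these, with Slc6a12 at 6.63 or more and Slc12a2 at 9.08. Cartilage (-0.69 and 0.05), endoplasmic reticulum stress (-0.39 and 0.35), interferon (-0.74 and 0.004) and immediate early genes (-0.51 and 0.24) had deposited and relative means of opposite sign. For Nfat5 the difference between the tissues depended on the scaling. In TonEBP +/- it was 0.40 as deposited (adjusted p = 0.382) but passed at 1.085 with array medians subtracted (0.0325) and at 1.29 with background medians subtracted (0.0112). In WT it was -0.02 (0.963), 0.72 (0.131) and 0.71 (0.128).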

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

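The results below stand out because the genotype change differed between AF and NP by the interaction test. The tests of marrow in AF, of the dissection border, of blood in NP, of array spread in NP and of NP tissue in AF were chosen only after the results were seen, and the spread test in AF, the Nfat5 neighbourhood and the splits of the arrays beforehand. Single arrays in groups of 3 were not tested as outliers.

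In all, 197 clusters passed the interaction. More positive in NP than in AF were Htra1 (2.85), Slurp1 (2.83), Serpina1e (2.66), Sbsn (2.42 as measured, at least 1.92 against the background level), Anxa8 (2.31) and the cartilage list (0.71). More negative in NP were Elane (-4.91), H2ac15 (-4.71), Camp (-4.50 as measured, at or below -3.98), Ncf1 (-4.39) and Mpo (-4.32). The lists more negative in NP were neutrophil (-3.15), cell cycle (-1.86), osteoclast (-1.82), mineralisation (-1.70), erythroid (-1.25), macrophage (-1.14), actin (-0.66), B cell (-0.65) and endothelial (-0.64), none with an adjusted p under 0.05 with an estimated correlation (smallest 0.105). The cartilage value was 1.19 without AF WT array 1 and 0.42 without AF WT array 3. Without AF TonEBP +/- array 3 the actin value was -0.44 and the endothelial list did not pass (-0.43, adjusted p = 0.0521). Of the 197 clusters 38, and of the mineralisation, osteoclast, B cell and endothelial lists 9 of 10, 7 of 8, 11 of 12 and 10 of 11 members, were clearly above background on no NP array, so a change in NP cannot be read for them and their values say no more than the change in AF.

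The first pattern weighed is the rise of the mineralisation, osteoclast, neutrophil and cell cycle lists in AF of TonEBP +/- mice with the fall of the cartilage list (-0.57; -1.05 without AF WT array 1, and not passing without AF WT array 3, -0.28, adjusted p = 0.117). None of these lists passed in AF with an estimated correlation (adjusted p = 0.276 for mineralisation and osteoclast, 0.495 for neutrophil and cell cycle, 0.534 for cartilage), so the pattern rests on camera's preset correlation. More vertebral marrow as a whole would raise red cell with neutrophil markers, but the neutrophil rise (0.996) less 2 times the erythroid change (-0.17) was 1.34 (SE 0.452), which argues against added marrow as the source of the neutrophil part. With arrays quantile normalized within each tissue, the mineralisation list still rose by 1.42 (SE 0.402, against 1.58 as deposited), over 2 SE from 0. The bound set beforehand, over 0.5 of the deposited change by 2 SE, was not reached, so wider array spread remains open as a cause. With the interquartile range as a covariate, chosen after seeing the data, 42 of the 51 genes named as passing in AF lost their call. The label of 13 named genes did not change, but these include genes that had not passed before, such as Cytl1 and Krt8. More bone and less disc tissue at the dissection border, and a change of AF cells with loss of 1 TonEBP copy, would both part the mineralisation from the cartilage list, which differed by 2.15 (SE 0.646), so both may hold.

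The second pattern is the fall of the neutrophil and erythroid lists in NP of TonEBP +/- mice. Less blood or marrow carried into these samples would lower genes that are low in NP itself, and 88% of the called clusters were higher in AF than in NP of WT mice, against 31.3% of all with array medians subtracted and 56.1% of all as deposited, so this explanation could account for the fall. Quantile normalization within each tissue, the test set beforehand for array spread, moved the list by only 0.0114 log2 on the median NP array and so tests nothing here. The NP arrays hardly differed in spread (interquartile range 3.61 to 3.8): stretching each about its median would bring the neutrophil list a change of 0.0729 (SE 0.0649), against a fall of 2.15, which argues against array spread as the source. A loss of blood cells throughout TonEBP +/- mice was not tested, and in AF the neutrophil list was higher by 0.996.

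The third pattern is the fall of 735 clusters in AF of TonEBP +/- mice, among them Krt19 and Acan, which are high in NP. Less NP tissue in these AF samples could bring the fall of 1.5% of them at most, given that the NP share in AF of WT was limited to 0.975%. This argues against less NP tissue as the source for most of these clusters. The limit was set from the keratins Krt8, Krt18 and Krt19, so for Krt19 this source remains open. The first pattern's border hypothesis (2.15, SE 0.646) may cover the 735 clusters as well.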

How the results depend on the processing

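With 3 arrays per group, and a median within-group SD of 0.364 log2 in AF, the counts of genes called between genotypes depended on single arrays and on the fit, while those between the tissues stayed within 1.5 times in each omission of 1 array but moved with 4 of the settings below, and their split by direction turned with the scaling. The direction of named genes that passed turned only with the marker covariates. No paired analysis was possible because the replicate numbers only follow the order of the samples and the labels do not tie AF and NP to a mouse. Dim clusters lay near the background, at 5.74 to 7.08 log2. Where not stated, the cause was not tested. Leaving out 1 array gave 81 to 4029 calls in AF, 2 to 79 in NP, 22 to 1319 for the interaction, 0 to 1033 averaged, 16298 to 17819 between the tissues in WT and 15198 to 16997 in TonEBP +/-. Nfat5 moved between -0.45 (without AF WT array 1) and 0.67 (without AF WT array 3) in AF and between 0.30 and 0.69 in NP, and never passed. Fits with trend or robust moderation kept all counts within 1.5 times, except averaged (2 with the trend). Array weights gave 7187 in AF, 81 in NP, 2503 for the interaction and 2408 averaged, but their estimation did not converge and gave AF TonEBP +/- array 1 a weight of 19.9. Covariates for marrow and muscle markers left 15 in AF, 0 in NP, 0 for the interaction, 0 averaged, and 0 and 1 between the tissues in WT and TonEBP +/-. These markers differ between the tissues and, for the neutrophil list, between the genotypes within each tissue (0.996 in AF, -2.15 in NP), so the covariates may take up the change itself. Each comparison's own arrays gave 3 in AF and 0 in NP, where fewer arrays give fewer degrees of freedom. The interquartile range covariate, chosen after seeing the data, gave 38 in AF, 72 in NP and 118 for the interaction. Quantile normalization gave 6 averaged and 10866 between the tissues in TonEBP +/- across 12 arrays, and 8 averaged within tissues. Subtracting array medians gave 13 in NP and 0 averaged. Among clusters above background, a restriction chosen after seeing the data, there were 2 averaged, 8237 of 10993 between the tissues in WT and 7435 of 10642 in TonEBP +/-, with fewer clusters tested, and 1705 in AF, 36 in NP and 175 for the interaction. Subtracting background medians, chosen after seeing the data, gave 13733 between the tissues in WT (7212 higher in NP) and 11086 in TonEBP +/- (7510 higher in NP), against 4921 and 4437 higher in NP as deposited. Nfat5 passed between the tissues in TonEBP +/- with array medians (1.085) or background medians (1.29) subtracted. Without dim clusters there were 11554 between the tissues in WT, with fewer clusters tested; 2 genes named in AF, 2 in NP and 1 between the tissues in WT were filtered out and have no value. An adjusted p under 0.1 gave 2691, 52, 451 and 2 in AF, NP, interaction and averaged, and an unadjusted p under 0.05 with a 2-fold change 223, 2035 and 90 in the last 3. The overlap of AF and NP was 320 at an unadjusted p under 0.05.

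Of the lists, 10 were called in AF (0 with an estimated correlation, 2 by fry, 7 to 13 leaving out 1 array), 7 in NP (4 with an estimated correlation, 4 with covariates, 6 to 10), 10 for the interaction (0, and 10 to 13), 8 averaged (0 with an estimated correlation, 0 by fry, 5 with covariates, 5 to 10), 13 between the tissues in WT (0 with an estimated correlation, 23 by fry, 13 to 15) and 14 in TonEBP +/- (0, and 12 to 14). Directions turned with the marker covariates for H2ac15 in the interaction (0.67), Mpo between the tissues in WT (0.21), Slc4a1 in TonEBP +/- (0.68), the neutrophil list in NP (0.20), interaction (-0.000182 as fitted, the test upwards), averaged (0.20) and tissues (0.28 in WT, 0.28 in TonEBP +/-), the cartilage list in WT (0.97) and the muscle list (1.34e-15 and 3.05e-15, 0 by construction, as its mean is a covariate). Among clusters above background, fibrous matrix genes turned in the test for the averaged effect (mean 0.07032, not passing, and 0.07032 with an estimated correlation). There the interaction called 11 of 19 lists, adding NP and notochord, glycosaminoglycan, fibrous matrix, hypoxia and immediate early lists as positive, and the averaged effect 6 of 19, adding NP and notochord, cartilage and cell cycle lists as lower. Tested with an estimated correlation, this restriction called 0 in AF, 4 in NP, 0 for the interaction, 0 averaged and 0 between the tissues in either genotype. By fry, fibrous matrix genes turned between the tissues (-0.77 in WT, -0.80 in TonEBP +/-), since fry does not compare with other genes.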

Other observations

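Genes of blood-forming cells were measured at high signal in the AF samples. The probe sets of the neutrophil granule genes Ngp and Lcn2 stood at the array maximum on all 6 AF arrays (group means 19.88 in WT and 19.93 in TonEBP +/-, n = 3 each). In NP, Ngp was 17.48 in WT (SD 0.75) and 15.33 in TonEBP +/- (SD 1.4), and Lcn2 16.16 (SD 1.2) and 13.80 (SD 1.7). Slc4a1 was 15.91 and 15.76 in AF and 12.00 and 8.97 in NP, and Alas2 14.36 and 13.52 in AF and 10.08 and 8.02 in NP, in WT and TonEBP +/-. These genes were chosen after their values were seen. Signals at the maximum, 19.86 to 19.93, are lower bounds, so changes of Ngp, Lcn2 and Actb in AF, and of Car3, at the maximum on 5 NP arrays, cannot be read.

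In AF the genotype change followed the level of signal. In 10 equal parts of the clusters by mean AF signal, the median change ran from -0.11 in the dimmest through -0.17 in the third to 0.39 in the brightest, and was 0.02 in the dimmest and 0.16 in the brightest after quantile normalization within tissues. Both directions of call were commonest in the brightest part (280 higher, 269 lower). Of the 612 clusters higher in AF of TonEBP +/-, 47.9% were higher in NP than in AF of WT mice, of the 735 lower 9.93%, and of all clusters 33.7%, with array medians subtracted. As deposited these shares were 35%, 8.98% and 22.2%. Both comparisons subtract the same AF WT arrays, so part of the difference between these shares is built in. These counts were made after seeing the data.

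The sex of the mice is not given, and Y-linked genes formed no clear groups: Eif2s3y ran from 7.26 to 9.93 log2 in AF and 7.41 to 10.3 in NP, Kdm5d from 5.78 to 7.20 (not clearly above background) and 7.73 to 8.37, and Uty from 7.95 to 9.16 and 9.38 to 10.0.

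Further tests of technical sources were made, of which the first was chosen after seeing the data. The shift of the background probe sets was 0.819 of the shift of the median cluster between NP and AF over both genotypes (0.67 of 0.82 log2), so most of that shift may come from scaling of the arrays. Strain DNA linked to the targeted allele would put changed genes near Nfat5. In the averaged effect the 50 genes around it had a mean absolute t of 1.19. The median over 18472 windows of 50 neighbouring genes was 1.08. A share of 0.208 of the windows was as large as around Nfat5, so the bound set beforehand, a share under 0.05, was not reached. A mean over 50 genes can miss a few changed ones, so this test cannot exclude linked strain DNA.

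The calls were compared with other splits of the same arrays. In AF, NP and both tissue comparisons, 1 of 10 splits (1, 1, 1 and 1, the real one) had as many calls, and the highest other split had 4, 1, 0 and 0; 10 splits are too few to put chance under 0.05. For the interaction 2 of 60 splits reached 197, the other with 355, a share under the bound of 0.05 set beforehand against chance. These 60 splits regrouped each tissue separately, so some can keep the genotype grouping in 1 tissue. Whether the split with 355 does was not tested, so it cannot show what a grouping other than genotype gives. For the averaged effect 9 of 60 splits had as many calls as the real one. Among these, a split with 197 averaged calls and 1 interaction call gave the real counts exchanged, as real AF labels with exchanged NP labels would. These splits are therefore not free of genotype and cannot decide whether the interaction count or the single averaged call is chance.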
